A study of Rattus norvegicus with 10 samples.

How the data were processed

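Immune cells were collected from the lungs of Sprague-Dawley rat pups on postnatal day 1. Their mothers had received lipopolysaccharide (LPS, a bacterial endotoxin) or normal saline into the amniotic sac on embryonic day 20. The labels give 10 libraries, 5 from the LPS group and 5 from the saline group. Per the labels' protocols, RNA was extracted with a small-scale column kit and made into stranded total-RNA libraries with a low-input kit, which were read from both ends. The labels do not state which dam or litter a pup came from, its sex, how the immune cells were isolated, or whether a library held 1 pup. The p-values below therefore measure only the spread between these libraries, and that spread can be smaller than the spread between litters.

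The submitters' processing notes name FastQC, cutadapt, Bowtie2, STAR, RSEM and edgeR, without versions or order. Genome build and annotation are not given in the sources used here. The authors deposited a table of 9318 rat Ensembl gene identifiers with a signal value per library, which the file's own name calls TMM-normalized counts (TMM, trimmed mean of M-values). That these are reads scaled to counts per library size (CPM) was read from the values, and no label states it. The column totals ran from 949212 to 1.10827e+06, so the values were not plain CPM of the listed genes. All 10 columns could be tied to a sample by the library name in the labels, leaving 0 columns without a sample. The 5th-highest value was at least 4.83 in every row. Genes that reach such a value in fewer than 5 libraries are therefore absent from the table, whether weakly expressed throughout or expressed in only a few libraries.

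Within each library, 100% of the values were whole multiples of a fixed step, within 0.001 of a multiple, and that step was taken as the value of 1 read. The search for the step was tested on simulated columns and found it in 20 of 20. The steps gave 23.8 to 32.3 M reads (M, mega) in the listed genes per library, with a median of 679 to 1062 reads per gene. A value of 0 in a library allowed up to 0.0888 to 0.14 CPM, the value of 3 reads. Such floors cover counting error only, since reads are not independent molecules. Count-based models were not run: the unit of the table was treated as a normalized signal.

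The values were transformed to log2(value + 0.993), the pseudocount being 1 CPM at the mean column total. Fold changes are on that scale, which understates the change of weakly expressed genes. A filter on a mean of at least 1 CPM removed no gene, and 9318 genes were tested. LPS was compared with saline with limma 3.58.1 in R 4.3.3, using a linear model with moderated variances that follow a trend in abundance, two-sided tests and Benjamini-Hochberg adjustment at 0.05. On data simulated for this comparison with 9318 genes, 200 of them changed, in 10 runs, the fit recovered 71.9% of the genes changed by 0.5 on the log2 scale, 93.6% of those changed by 1 and 99.2% of those changed by 2. Of the simulated genes called, 4.60% were unchanged ones. The simulation drew genes independently, without litter effects, and changed fewer genes than were called in the data. Its shares may therefore differ from the real ones.

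Gene lists for inflammatory, interferon, metabolic and cell cycle processes and for cell type markers were fixed before the data were examined. The table gives identifiers without gene names, and the RefSeq gene table of the GRCr8 assembly used here has no entries in its Ensembl column, so 0 of 9318 identifiers could be matched. The lists and a covariate made from Y-linked genes were therefore not run. The rule for named genes, also fixed before the data were examined, took the genes with the largest fold change in each direction among those with adjusted p under 0.05 and no overlap between the groups, and required a gene symbol. With no symbols it was applied without that condition, and the first 2 genes per direction are given by identifier. Their names are not paired with the identifiers in the sources used here.

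Distances between libraries were root mean square differences of the log2 values. They, the read totals and the share of reads in the most abundant genes were compared with exact permutation tests over the splits of the libraries into 5 and 5. The response of each library was computed from genes called in a fit to the other 9 libraries, as the slope of its deviations from the saline mean against the fitted fold changes, so that 0 corresponds to the saline mean and 1 to the fitted LPS change. Alternatives covered the pseudocount, the filter, the scaling, the variance model, library weights, the threshold, a rank test, the replicate number as a block and each library left out in turn. Further alternatives were added after seeing the data: covariates for a split of the libraries by genes present or absent and for the share of the most abundant genes, thinning of reads to the smallest TMM-scaled library size, at which 1 read is worth the same CPM in each library, identical rows counted once, and removal of saline library 3 with LPS library 1. A gene counted as switching between libraries when every library was either at 5 or more or below 0.6 CPM. Those limits were also set after seeing the values.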

Results

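RNA was sequenced from lung immune cells of newborn rats whose mothers had received an intra-amniotic injection of LPS or of normal saline on embryonic day 20, with collection on postnatal day 1. Each group held 5 libraries, and all libraries of a group share a library-name prefix that the other group lacks. What the prefix marks is not stated, so the libraries of a group may not be independent replicates of the treatment. The saline libraries held 27.6 ± 3.11 M reads in the listed genes (SD, n = 5), and the LPS libraries 25.7 ± 2.13 M (SD, n = 5). The difference of -1.95 M was within the spread between libraries (exact two-sided permutation p = 0.222, n = 5 per group).

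The comparison of LPS with saline asks how RNA levels in the collected lung immune cells differ after prenatal exposure to endotoxin. Each library measures all its cells together, and the cell type marker lists were not run. Changes within cells and changes in the mix of cells were therefore not told apart. In the LPS group, 491 genes were higher and 412 were lower than in the saline group, 903 of the 9318 genes tested (9.69%, limma, adjusted p under 0.05). Most changes were small. The median log2 fold change was 0.51 among the genes that rose, with quartiles of 0.34 and 0.81, and -0.39 among those that fell, with quartiles of -0.55 and -0.30. A change of at least 1 on the log2 scale was reached by 119 of the called genes, 86 higher and 33 lower. With the deposited scaling most of these were therefore increases, but the largest fold changes among the 4 named genes were decreases. The balance of these larger changes was not counted with another scaling. The median half-width of the 95% confidence interval of a gene's log2 fold change was 0.20. Without saline library 1 the count was 588 genes, and in an exact rank-sum test per gene 0 genes passed, the 4 genes named here included (smallest adjusted p = 0.0895). These 4 genes did not overlap between the groups, so they already had the smallest p-value that the rank-sum test can give. It therefore cannot decide about them.

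More of the genes with high values than of those with low values were called. Levels are given in TMM-normalized counts, in the unit CPM. Of the 3106 genes with the lowest mean values (3.47 to 18.3 CPM), 127 rose and 102 fell. Of the 3106 genes in the middle, 152 rose and 148 fell, and of the 3106 with the highest means (55.4 to 85940 CPM), 212 rose and 162 fell. The 5 LPS values lay entirely above or below the 5 saline values in 826 genes (8.87%, against 0.794% by chance), and 626 of these were among the called genes.

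**Figure D1:**
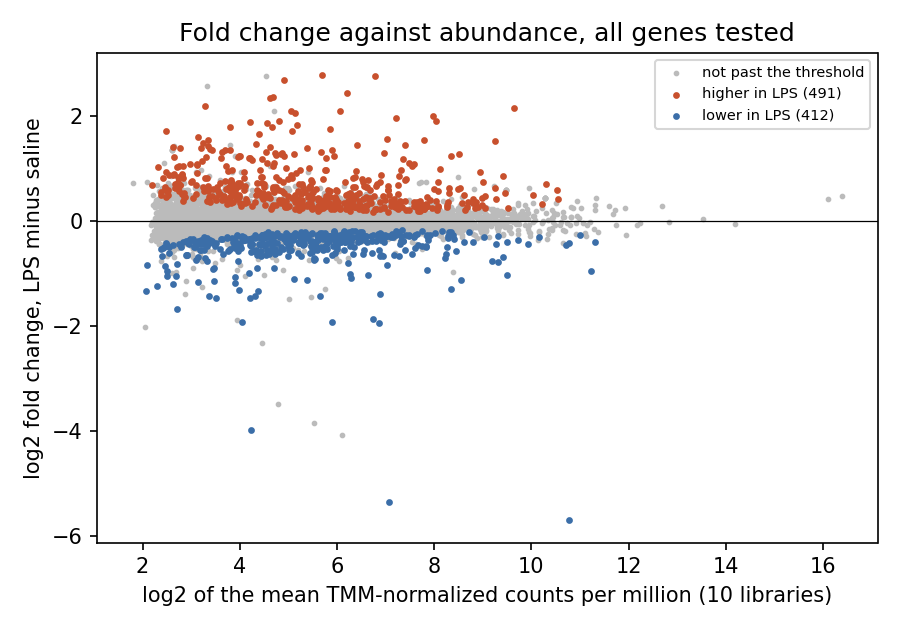
Log2 fold change of LPS over saline (y axis) against the log2 mean value in TMM-normalized CPM (x axis), 1 point per gene, colored where limma's adjusted p was under 0.05. The 491 genes higher and 412 genes lower in LPS lie across most of the range of abundance.

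The pair of genes that fell furthest had far lower values in each LPS library than in any saline library. ENSRNOG00000045654 fell from 3438 ± 1548 to 65.8 ± 41.4 CPM (SD, n = 5 per group), a log2 fold change of -5.71 with a standard error of 0.48 (limma, adjusted p = 1.0e-04). ENSRNOG00000050647 fell from 265 ± 156 to 4.57 ± 2.49 CPM (SD, n = 5 per group), a log2 fold change of -5.36 with a standard error of 0.53 (limma, adjusted p = 2.1e-04). Both genes had their lowest saline value in saline library 4, at 933 and 46.4 CPM, still above every LPS library. The highest LPS values were 133 and 7.74 CPM, both in LPS library 4.

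ENSRNOG00000013973 rose from 13.9 ± 9.92 to 89.6 ± 35.4 CPM (SD, n = 5 per group), a log2 fold change of 2.78 with a standard error of 0.51 (limma, adjusted p = 0.0055). ENSRNOG00000050586 rose from 24.6 ± 6.96 to 196 ± 108 CPM (SD, n = 5 per group), a log2 fold change of 2.76 with a standard error of 0.39 (limma, adjusted p = 0.0013). LPS library 2 had the lowest LPS value of both, 29.9 and 56.7 CPM, above the highest saline values of 25.7 and 32.1. With the share of reads in the 2 most abundant genes as a covariate, their log2 fold changes were 2.00 and 1.78 and neither passed (limma, adjusted p = 0.173 and 0.0779). That share ran from 12.5% to 14.4% in saline and from 14.8% to 21.7% in LPS libraries. A covariate so tied to the group is hard to separate from treatment, so the lost calls do not decide the cause.

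**Figure D2:**
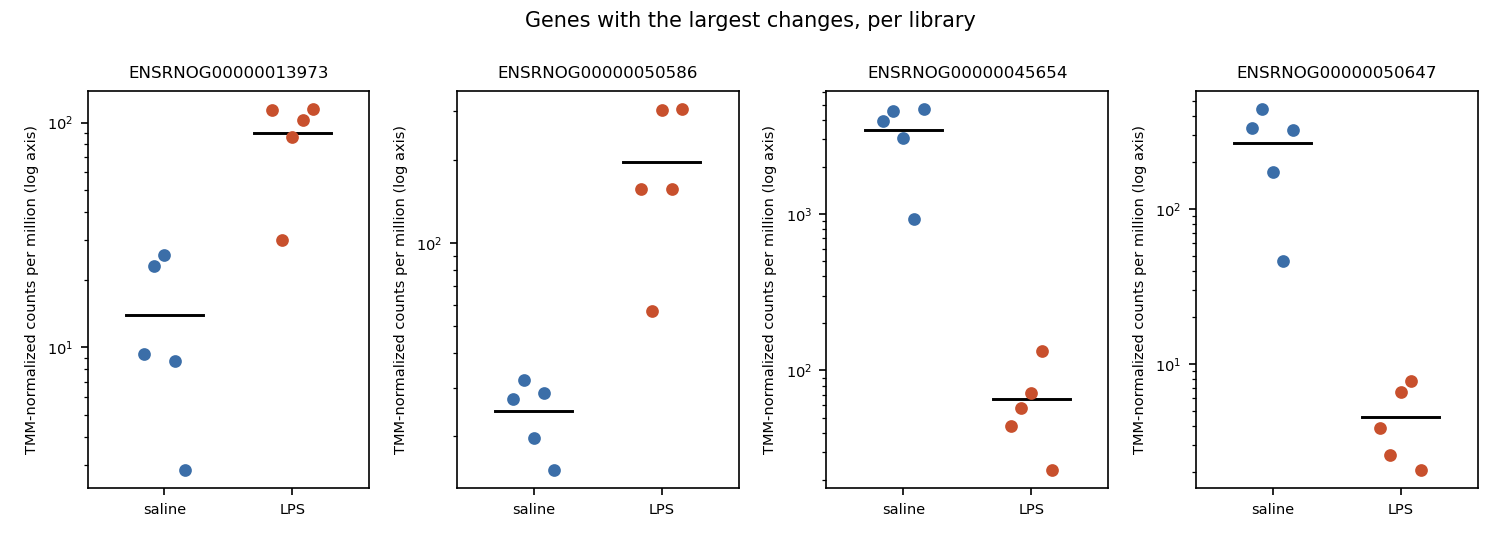
Values in TMM-normalized CPM (log axes, a separate scale per gene) of the genes with the largest changes, 1 point per library and a line at the group mean. No LPS library overlaps a saline library in any of the 4 genes.

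The groups separated along the first principal component, which held 38.3% of the variance, while the second held 12.8%. Libraries of different groups were 0.42 log2 units apart on average, against 0.311 within saline and 0.323 within LPS. The excess of the distance between groups was the largest of the 126 splits (exact one-sided permutation p = 0.00794, n = 5 per group), the smallest p that the splits can give. The spread within the LPS group did not differ detectably from that within saline (difference 0.0128, exact two-sided permutation p = 0.571, n = 5 per group).

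**Figure D3:**
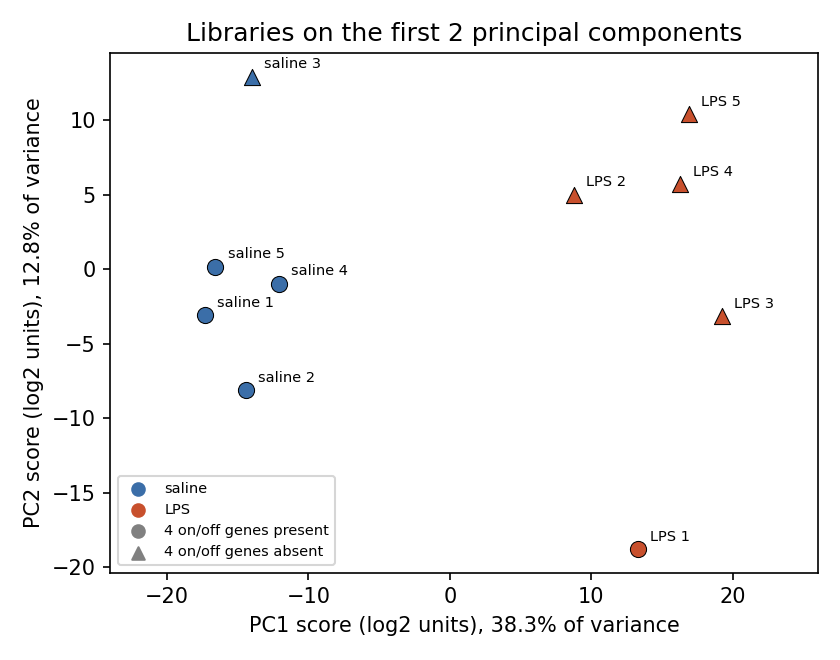
Scores of the 10 libraries on the first (38.3% of variance, x axis) and second (12.8%, y axis) principal components of the log2 values, in log2 units. Colors mark the groups, and shapes mark whether the 4 genes with the switching pattern were present, circles for present and triangles for absent. The groups separate along the first component, and on the second the circles and triangles differ by 12.3 on average (exact two-sided permutation p = 0.0317), against 0.589 without the 5 genes of that pattern (exact p = 0.937).

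The response size was 0.871 ± 0.162 in LPS (SD, n = 5), from 0.675 in LPS library 2 to 1.05 in LPS library 3, where 0 is the saline mean and 1 the change fitted from the other 9 libraries. In 1000 resamplings of the genes, the value of LPS library 1 (0.727) ran from 0.427 to 0.94. The response size was 0.139 ± 0.12 in saline (SD, n = 5). The 5 genes that split the libraries, described below, were not left out of the genes used, and they may have moved the values of LPS library 1 and saline library 3. Of the genes called from the other libraries, 94.9% to 97.5% lay on the LPS side of the saline mean in each LPS library, and 50.1% to 69.0% in each saline library.

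The 2 most abundant genes took 17.6% ± 2.87 of the reads in LPS libraries and 13.6% ± 0.896 in saline libraries (SD, n = 5 per group). The difference was 4.05 percentage points (exact two-sided permutation p = 0.00794, n = 5 per group), with no overlap between the groups. With this share as a covariate in the fit, 132 genes passed in place of 903, 115 of them shared. The fold changes of the 903 genes kept their sign with the covariate, at a median ratio of 0.915 to those without it, while their median standard error went from 0.0973 to 0.137. Rescaling every library to the same column total gave 302 genes higher and 960 lower. The share of increases was then 23.9%, against 54.4% with the deposited scaling. Quantile normalization gave 434 higher and 479 lower, a share of 47.5%, and with median-ratio rescaling the share was 54.0%. The balance of increases and decreases therefore depends on the scaling.

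A small set of genes was present in some libraries and absent from others, in a pattern that followed the treatment only in part. In saline libraries 1, 2, 4 and 5 and LPS library 1, 4 genes had means of 8.29 to 138 CPM, and in saline library 3 and LPS libraries 2 to 5 they were at or near 0. A 5th gene had the opposite pattern, at 45.1 ± 6.75 against 1.51 ± 0.661 CPM (SD, n = 5 libraries each). The pattern was present in 4 of 5 saline and 1 of 5 LPS libraries (Fisher's exact test, two-sided p = 0.206, n = 5 per group). Within either set of libraries the comparison of LPS with saline had 1 library on one side. With the split as a term in the fit, 546 genes passed, 455 of them shared with the 903. Without saline library 3 and LPS library 1, 477 genes passed, 435 of them shared. The fits with these terms and without these libraries were chosen after seeing the data.

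**Figure D4:**
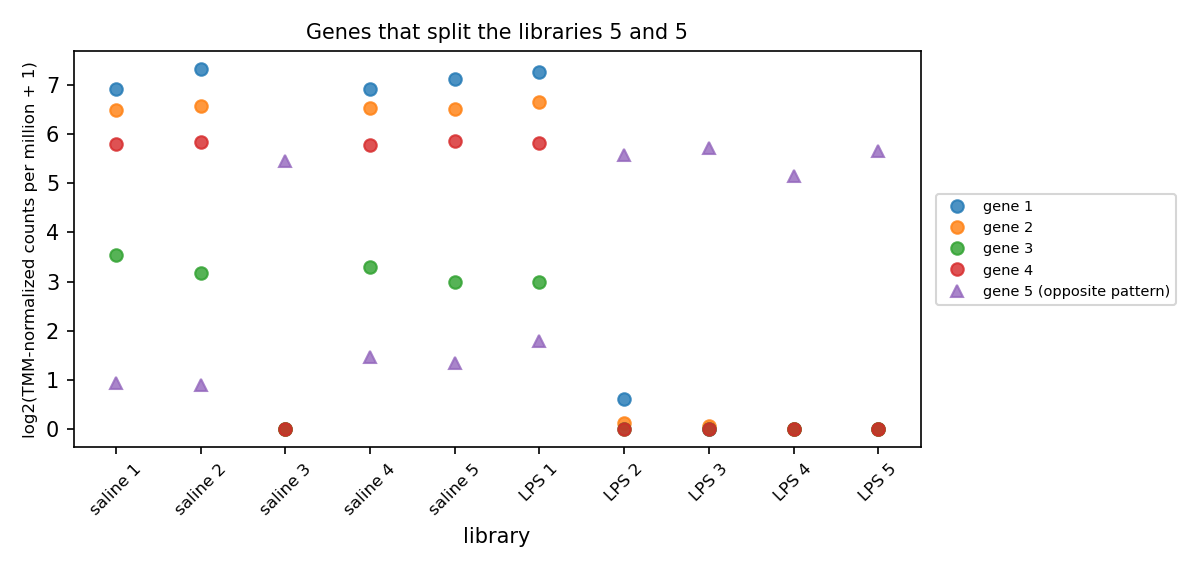
Log2(value + 1) of the 5 genes that split the libraries into 5 and 5 (y axis, TMM-normalized CPM) in each of the 10 libraries (x axis), 1 point per gene and library. In saline library 3 the 4 genes present in the other saline libraries are at 0, and LPS library 1 alone among the LPS libraries holds them.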

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

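The tests of the library-name prefix, of a fixed split of reads between the pair of fallen genes, of exchanged libraries (both of them) and of pup sex were chosen only after the result was seen. The covariates, the thinning and the removal of libraries were also added then; the bounds for the covariate and thinning tests were written before their values were known, but after the 903 calls had been seen.

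Among 24 groups of 5 values checked for a library far from the others, 8 had one, all in the 5 genes that split the libraries. Chance gives about 1 in 20 groups, but these genes were picked for their pattern, so their distant values follow from that choice. Saline library 3 was at 0 for genes 1, 2 and 4, against at least 119, 88.8 and 54.0 CPM in the other saline libraries, and at 42.9 for gene 5, against at most 1.78. LPS library 1 was at 152, 99.3, 6.91 and 55.5 CPM for genes 1 to 4, against at most 0.532, 0.0818, 0 and 0 in the other LPS libraries.

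The number of genes changed between LPS and saline was weighed first. Of 100 splits of the libraries drawn, 1 gave as many genes, the real one with 903, and the highest other gave 13. This argues against a chance split of libraries taken as independent. It cannot address a difference between litters, since the splits treat each library as its own unit. Thinning until 1 read was worth the same in CPM in each library left at least 845 genes, and with the switching split as a term the fold changes of the called genes had a median ratio of 1.041 to those without it, which argue against depth and that split as the whole cause. With the share of the 2 most abundant genes as a term the median ratio was 0.9151, with quartiles of 0.755 and 1.09, so the term did not remove the changes, but the calls were not kept: 132 genes passed, as the median absolute log2 fold change went from 0.438 to 0.415 and the median standard error from 0.0973 to 0.137. All saline libraries carry the same library-name prefix and all LPS libraries carry another, with 0 prefixes in both groups. The labels do not state what the prefix marks. A difference in preparation, dam or litter marked by it may contribute and cannot be told apart from the effect of LPS. If it marks a dam, the libraries of a group would not be independent replicates of the treatment.

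The pair of genes that fell furthest was weighed next. The ratio of reads of the 2 genes ran from 10.3 to 22.3 over the libraries, with a dispersion index of 175 against counting error alone, and since libraries can differ by more than counting error this does not decide whether both genes share reads. With the switching split as a term, the smaller of the 2 ratios of fold changes was 0.987, so the split does not account for the fall. A difference marked by the prefix or between litters may account for it and stays open, since 0 prefixes occur in both groups and litters are not given in the sources used here.

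For the genes that split the libraries 5 and 5, weighed last, 4 of 9313 other genes passed for the split beside the group (0.043%, limma; 501 at an unadjusted p under 0.05), from 1 without saline library 3 to 8 without saline library 5, which argues against a broad library batch. The second principal component differed between the sets of libraries by 12.3 (exact two-sided permutation p = 0.0317), but by 0.589 when computed without these 5 genes (exact p = 0.937; 0.151 and 0.468 for the next components), a check chosen after the component was seen. An exchange of saline library 3 with LPS library 1 was tested first by their response sizes, 0.7267 for LPS library 1 and 0.253 for saline library 3. In 1000 resamplings of the genes these reached 0.427 and 0.51, past the bound of 0.5 set for each, so that test did not decide. The 5 switching genes were not left out of the genes it used, so the pattern in question may itself have moved both values. With both labels exchanged 13 genes passed, and 8 to 20 with 1 library left out. With the labels as given these counts were 903 and 588 to 908, which argues against the exchange. This test was added after the first had left it open and its count of 13 was known. The exchanged labels are the switching split itself, so the 13 genes may include the 5 that define it. The highest count among the other splits drawn was also 13, with 1 library exchanged, and may be the same fit. Pup sex may also produce such a pattern, and with 5 genes of unknown name and position it stays open.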

How the results depend on the processing

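The covariates, the thinning, the single counting of identical rows and the removal of saline library 3 with LPS library 1 were chosen only after the data were seen. The count of 903 changed genes stayed within 1.5 times in 22 of 29 alternatives. It was 119 with a log2 fold change of at least 1 required, 309 at an adjusted p under 0.01, 546 with the switching split as a covariate, 132 with the share of the 2 most abundant genes as a covariate, and 477 without saline library 3 and LPS library 1. The exact rank-sum test gave 0 genes, with a smallest adjusted p of 0.0895, beside 2404 genes at an unadjusted p under 0.05 in limma: with 5 libraries per group its p-values take few levels. Leaving out 1 library gave 588 (without saline library 1) to 908 genes, and the genes lower in LPS numbered 256 without saline library 1 and 266 without saline library 3, in place of 412. The first 2 thresholds count fewer genes by construction and the removals use fewer libraries; for the other changes the cause was not tested, beyond the larger standard errors with a covariate. Rescaling to equal column totals moved the median of all genes to -0.0896 and gave 1262 genes. With the replicate block 686 genes passed. The block was planned as an alternative only, since no label says that shared numbers mark a dam, litter or day. Same-numbered libraries correlated at -0.178 to 0.168. Among the 5 libraries of the other group, 4 of 10 libraries correlated best with their own number. These values do not decide whether the numbers mark pairs.

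Each named gene kept its direction in the alternatives that moved its fold change, 20 for each raised gene and 19 for each fallen gene; the others of the 29 left the fold change as it was. All lost their call in the rank-sum test, and the raised genes also with the share covariate, at adjusted p of up to 0.173 for ENSRNOG00000013973 and 0.0895 for ENSRNOG00000050586. The distance between groups passed in 16 of 16 alternatives and the difference in the share of the 2 most abundant genes in 10 of 10. Leaving out the filter removed nothing and tested nothing. Gene lists, the Y-linked covariate and count models were not run. Thinning to equal TMM-scaled library size gave 868 genes. Genes expressed below the lowest levels in the table were not analysed here.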

Other observations

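The limits for a switching gene were set only after the values were seen. Of 14 genes that met them, 4 shared the pattern described above and each of the other patterns held 1 gene. Genes absent from more than 5 libraries could not be seen, since every row of the table has its 5th-highest value at 4.83 or more. Single genes were absent from saline library 1, saline library 3, LPS library 1, LPS library 4 or LPS library 5 alone, with means of 10.4 to 33.0 CPM in the libraries that held them.

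The table holds 47 rows in 16 sets whose values are identical in all 10 libraries, the largest set with 6 rows. Counted once each, 915 of 9287 genes passed, 901 of them shared with the 903.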
